A study of Arabidopsis thaliana with 4 samples.

How the data were processed

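Per the labels, the 4 samples were Arabidopsis thaliana Col-0 wild-type seedlings in 2 groups of 2, darkness and red light. Per the labels' protocols, RNA was extracted with a plant kit, treated with DNase I, enriched for poly(A) RNA on oligo(dT) beads and made into libraries by standard Illumina protocols. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting program, the use of strand and the treatment of reads that match several genes are not given in the sources used here.

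Per the file headers, the authors deposited a read column and an RPKM column for each condition, over 27416 gene models with 1 Phytozome transcript per locus. The deposited estimated counts were whole numbers, except that 0.5 stood where no read was counted, in 4059 genes in darkness and 4164 in red light. These were set back to 0 here, and all other read values were used as deposited. The deposited RPKM values were computed by the authors from those reads per length of gene model and per total reads. Recomputing them showed that they were scaled to the sum of the whole reads in each column. The implied gene lengths were whole within 0.01 bases, and 99.99% were multiples of 3, so they are coding lengths without untranslated regions. A gene with long untranslated regions may therefore carry more or fewer reads than its length predicts. Whether this is equal in both conditions was not examined. Each condition had 1 column, and whether it pools both replicates or holds 1 library is not given in the sources used here. It was printed as the authors' value, with no SD.

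Depth was 41106535 reads in darkness and 33521717 in red light, 1.23 times as many in darkness. At the median coding length of 1047 bases, 10 RPKM corresponded to 430 reads in darkness and 351 in red light, and a floor of 3 reads to 0.0697 and 0.0855 RPKM. The ratio of RPKM values was given an exact 95% interval (Clopper-Pearson, from the binomial share of a gene's reads in each column). Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

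The planned test, edgeR's quasi-likelihood test on 4 samples, could not be used because each condition had 1 column. The fallback written before the data were examined was used. A gene was called at a 2-fold difference on RPKM + 1 (a log2 change of 1) with at least 10 RPKM in the higher condition. Fold values in the text are ratios of RPKM without the added 1, whereas log2 changes include it and understate the change of low genes. Gene lists, 27 with the plastid and mitochondrial genes, were fixed before the data were examined. A list's median log2 change was ranked among 10000 random lists of equal size drawn from the same 20 bins of mean expression. Lists outside the central 95% of the random medians were counted as standing apart.

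Named genes followed a rule fixed at the same time. It took the 12 called genes with the largest rise and the 12 with the largest fall, up to 2 called members of each list in each direction by size of change, and 15 genes named whatever their result. These 15 were PHYA, HY5, PIF3, PIF4, PORA, PORB, LHCB1.3, RBCS1A, HEMA1, CHS, PIL1, ATHB2, IAA19, ACT2 and UBQ10. The rule also asked that samples of the groups do not overlap, which could not be applied with 1 column each. Members outside the rule (LHCA2, LHCB4.1, LHCB4.2, PAL1, PAL2, C4H, ACO1, GI, SPCH, RD29A and RD29B) were chosen after their values were seen. So were the summed copies of LHCB1, LHCB2 and RBCS genes and the genes of the closing observations.

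Gene names and descriptions came from the RefSeq annotation of TAIR10.1, which matched 26719 of the 27416 loci. It matched 26691 by transcript identifier, and 96.6% of these had the same coding length. Plastid and mitochondrial identifiers were not paired with names and are given only as groups. Genes with at least 25% of their coding 31-base words in another gene were treated as having an uncertain split of reads, as were genes whose coding sequence lies inside the span of another gene.

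The calls were recomputed with TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, upper-quartile factors, quantile normalization, other minimum values, a pseudocount of 0.1, a 4-fold threshold, a rule on the whole counting interval, and without organelle, shared-sequence or photosynthesis genes. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The calling rule was tested on simulated data for the red-light comparison, with reads drawn for 27416 genes at the real depths. Of 50 genes each, it called 50 with a 4-fold rise, 50 with a 3-fold rise, 48 with a 4-fold fall and 50 with a 3-fold fall, and 0 of 27216 genes without a change. Of 200 random lists of 20 genes, 5.5% fell beyond the 2 percentile limits. The simulation held counting error alone, so it says nothing of variation between samples. Changes were planted only in genes of at least 10 RPKM in darkness and lay beyond the 2-fold threshold. Their detection, and the absence of calls without a change, were therefore nearly assured. For the calling rule, changes near 2-fold were not simulated.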

Results

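The series holds 4 samples of Arabidopsis thaliana Col-0 wild-type seedlings, 2 grown in darkness and 2 in red light of 60 µmol per square metre per second. Seeds were kept at 4 °C for 4 days on half-strength Murashige-Skoog medium with 1% sucrose and given 12 h of white light. They then stayed 4 days in darkness or red light, for a growth time of 4.5 days. Poly(A) RNA from whole seedlings was sequenced on an Illumina platform. The files carried 1 column of read counts and 1 of RPKM (reads scaled to the length of the gene model and to the total reads) for each condition, and did not say how the 2 replicates entered it. The dark column summed to 41106535 reads and the red-light column to 33521717, over 27416 gene models. The median gene had 287 reads in darkness and 242.5 in red light. No value therefore had a replicate error, no difference had a replicate check, and no p-value was computed. Intervals in brackets are exact 95% intervals that cover counting error only.

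The comparison asked which transcripts differ between seedlings grown in red light and in darkness. MSRB6 (AT4G04840), a methionine sulfoxide reductase that repairs oxidised methionine, showed the largest rise on RPKM + 1, from 1.63 to 199.6 RPKM in red light, a ratio of 122 (86.0 to 180.3). Ratios without the added 1 were higher for some genes with few reads in darkness, such as AT1G26761 (536) and GA2OX1 (217). ELIP1 (AT3G22840) and ELIP2 (AT4G14690), early light-induced chlorophyll-binding proteins that protect against excess light, rose from 33.5 to 2333 RPKM and from 33.4 to 2059 RPKM. BBX23 (AT4G10240), a B-box zinc finger protein of light signalling, showed the largest fall on RPKM + 1, from 116 to 0.427 RPKM, 272-fold (132 to 677). XTH15 (AT4G14130), a xyloglucan endotransglucosylase that remodels the cell wall, fell 32.4-fold (31.3 to 33.6), from 3406 to 105 RPKM.

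Of 12625 genes with at least 10 RPKM in either condition, 1097 were called higher and 676 lower in red light, at a 2-fold difference on RPKM + 1. Of the calls, 61.9% were higher. The ratio of RPKM values reached 10-fold in 116 of the higher and 36 of the lower calls. The 95% counting interval of the RPKM ratio excluded 1 for all 1773 calls. This follows largely from the 2-fold rule and the minimum of 10 RPKM and is no separate evidence. The median log2 change of the 12625 genes was -0.11. These calls compare 2 columns of values, and variation between seedling batches is not measured by them.

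**Figure D1:**
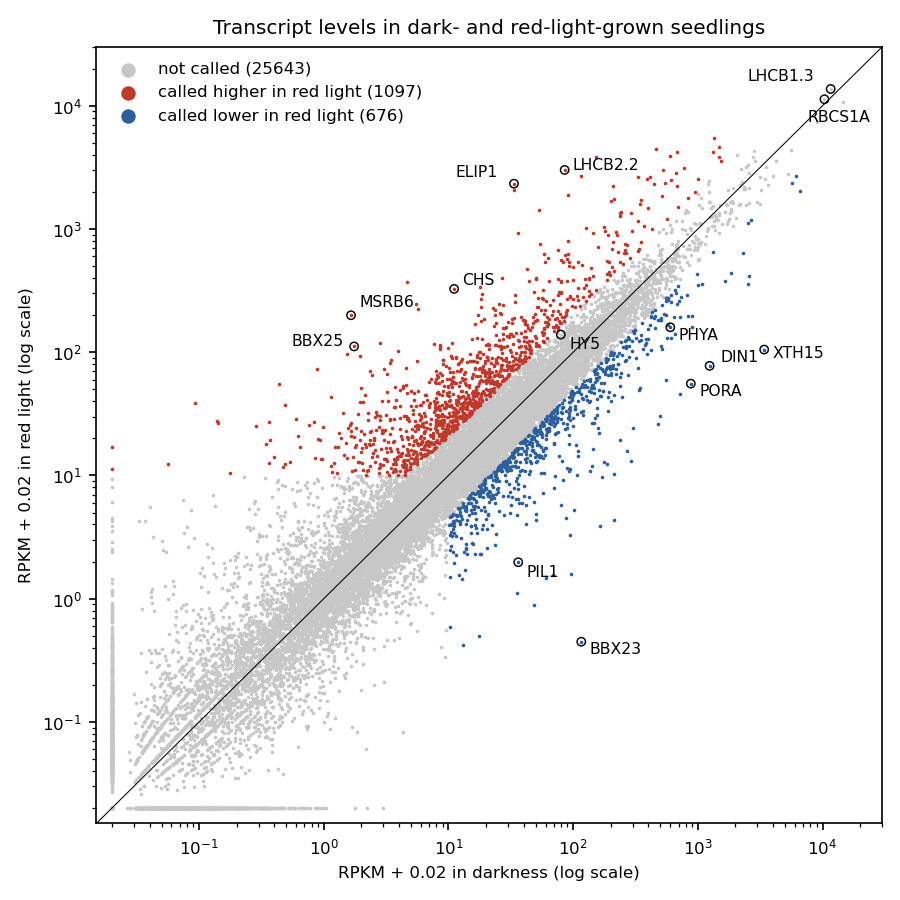
RPKM of each of the 27416 gene models in darkness (x axis) and in red light (y axis), both on log scales with 0.02 added, with 1097 genes called higher in red, 676 called lower in blue and the rest in grey. ELIP1 and LHCB2.2 lie far above the line of equal values, BBX23 and XTH15 far below it, and LHCB1.3 and RBCS1A close to it at the top.

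The other 9 of the 12 largest rises, also ranked on RPKM + 1, were as follows. FBA5, a fructose-bisphosphate aldolase, rose 84.6-fold to 72.6 RPKM, and AT5G48490, annotated as a lipid-transfer-like protein, rose 80.5-fold to 371 RPKM. BBX25, a B-box partner of the transcription factor HY5, rose 64.4-fold (48.8 to 86.7), from 1.73 to 111 RPKM. FADA, a desaturase of plastid phosphatidylglycerol, rose 64.3-fold to 96.5 RPKM. THI2.2, a thionin of the antimicrobial peptide class, rose 132-fold from only 7 reads in darkness (63.8 to 330). AT1G26761, annotated as an arabinanase or invertase, rose from 4 reads to 1747 reads, a ratio of 536 (209 to 1968). AT3G56290, annotated as a potassium transporter, rose 44.8-fold, CDSP32, a plastid thioredoxin-like protein of drought stress, 39.4-fold, and LHCB2.2, an antenna protein of photosystem II, 35.3-fold. LHCB2.2 shares 55.2% of its coding 31-base words with another gene, so its share of the reads is uncertain.

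Among the other 10 of the 12 largest falls, 6 had a name. CYP96A5, a cytochrome P450, fell 55.5-fold from 48.6 RPKM in darkness, and GRF7, a growth-regulating transcription factor, 45.0-fold from 68.5 RPKM. BETA-TIP, a vacuolar water channel best known from seeds, fell 41.6-fold (30.3 to 58.7), from 60.2 to 1.45 RPKM. BBX17, another B-box protein, fell 21.9-fold from 289 RPKM, and SNRK2.5, a protein kinase of the SNF1-related family, 20.5-fold from 212 RPKM. BCAT2, a branched-chain amino acid transaminase, fell 18.1-fold from 475 RPKM. The 4 without a name were AT4G25580, annotated as a CAP160 protein (42.5-fold lower), AT5G44260, annotated as a zinc finger protein (61.1-fold lower), AT5G02540, annotated as an NAD(P)-binding protein (49.0-fold lower), and AT5G57760, uncharacterized (28.8-fold lower). In the TAIR10.1 annotation 47.1% of the BETA-TIP, 41.4% of the AT5G57760 and 27.7% of the XTH15 coding sequence lay inside the span of another gene, on either strand. Whether reads were counted by strand is not given in the sources used here, so these 3 values are uncertain.

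**Figure D2:**
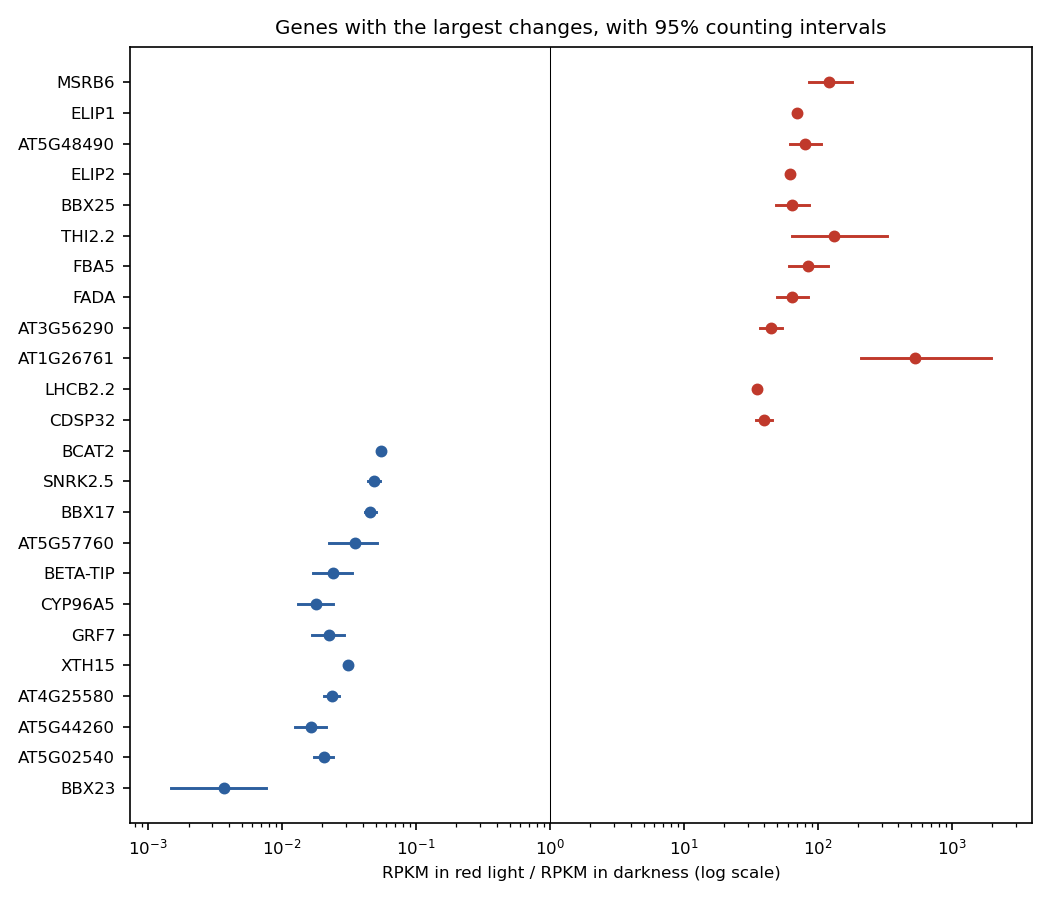
Ratio of RPKM in red light to RPKM in darkness (log scale) for the 12 genes with the largest rise (red) and the 12 with the largest fall (blue), ordered by their change on RPKM + 1, with lines for the exact 95% counting interval. Intervals are wide where few reads were counted, as for AT1G26761 with 4 reads in darkness and BBX23 with 7 reads in red light, and narrow for ELIP1 and XTH15.

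The genes were located in the TAIR10.1 assembly through their transcript identifiers, since the files gave no coordinates. MSRB6 lay on chromosome 4 from 2449434 to 2451651 on the plus strand, and ELIP1 on chromosome 3 from 8084405 to 8085669 on the minus strand. CHS lay on chromosome 5 from 4488476 to 4490264 on the plus strand. PORA was at 21990864 to 21992814 of chromosome 5, XTH15 at 8137020 to 8138392 of chromosome 4 and BBX23 at 6368829 to 6369950 of chromosome 4, these 3 on the minus strand. For these 6 genes the coding length in the reference equalled the length implied by the deposited values.

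For each gene list fixed beforehand, the median log2 change was ranked among 10000 random lists of the same size matched on mean expression. The percentile describes these columns and is not a test of the conditions. Of 27 lists, 14 lay above and 7 below the central 95% of the random medians. Lists of genes drawn independently would place 0.675 on each side, and genes that vary together could exceed these limits more often. Members called neither higher nor lower are given as not called, and members below 10 RPKM in both conditions could not be called.

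Antenna and photosystem genes of the nucleus were mostly higher in red light, and about as many Calvin cycle genes rose as were not called. Of 20 light-harvesting antenna genes, which bind chlorophyll and pass energy to the photosystems, 18 rose, none fell and 2 were not called, with a median log2 change of 2.01 (percentile 100). Under quantile normalization 16 rose, the calls of LHCB4.1 and LHCB4.2 having ended. LHCB2.2 rose from 85.4 to 3015 RPKM and LHCB2.3 from 52.7 to 1434 RPKM, 27.2-fold (25.9 to 28.6). LHCB1.3, the most abundant antenna transcript, was not called at 11628 RPKM in darkness and 13693 RPKM in red light, a ratio of 1.18 (1.17 to 1.18). The other antenna gene that was not called, LHCA2, was at 1058 and 1798 RPKM. Copies of LHCB1, like LHCB2.1 and LHCB2.2, share long stretches of coding sequence, which leaves the split of reads between them uncertain. The summed reads of LHCB1.1 to LHCB1.3 gave a ratio of 1.48 (1.47 to 1.49), those of all 5 LHCB1 genes 1.84 and those of the 3 LHCB2 genes 28.1.

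Of 22 nuclear photosystem subunits, 16 rose, none fell and 6 were not called (median log2 change 2.15, percentile 100). PSAH2, a subunit of photosystem I, rose 20.8-fold (19.8 to 21.9), from 91.4 to 1901 RPKM. PSBO2, a protein of the oxygen-evolving complex, rose 8.85-fold (8.52 to 9.19). Of 19 Calvin cycle genes, 10 rose, none fell and 9 were not called (median 1.19, percentile 100). CP12-2, which regulates the cycle by binding its enzymes, rose 18.7-fold from 18.0 to 337 RPKM, and FBA1, a plastid aldolase, rose 6.90-fold to 623 RPKM. RBCS1A, the main small subunit gene of Rubisco, was not called at 10360 RPKM in darkness and 11296 RPKM in red light. RBCS1B, RBCS2B and RBCS3B share much of their sequence, and their summed reads gave a ratio of 2.97 (2.95 to 2.99). The 61 genes of these 3 lists took 3.78% of all reads in darkness and 9.86% in red light.

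Pigment pathways showed rises with a few steep exceptions. Of 24 chlorophyll biosynthesis genes, 12 rose, 2 fell and 10 were not called (median log2 change 1.06, percentile 100). The 2 that fell were PORA and PORB, protochlorophyllide oxidoreductases known to be abundant in etiolated tissue. PORA fell from 878 to 55.6 RPKM, 15.8-fold (15.2 to 16.5), and PORB from 827 to 196 RPKM, 4.22-fold. PORC, the third member of that enzyme family, rose 9.64-fold from 8.94 to 86.2 RPKM. HEMA1, the glutamyl-tRNA reductase that starts the pathway, rose 7.01-fold (6.81 to 7.21), from 80.4 to 564 RPKM. GUN4, an activator of magnesium chelatase, rose 8.98-fold to 537 RPKM, although all of its coding sequence (100%) lay inside the span of another gene. Of 14 carotenoid genes, 8 rose, none fell and 6 were not called (median 1.22, percentile 100). PSY, phytoene synthase at the entry of the pathway, rose 8.65-fold to 293 RPKM, and ZEP, zeaxanthin epoxidase, rose 5.90-fold to 177 RPKM.

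Flavonoid genes included some of the steeper rises. Of 22 members, 9 rose, none fell and 13 were not called, 10 of these 13 with less than 10 RPKM in both conditions (median log2 change 1.86, percentile 100). This median depends on the low members, and was 3.35 over the 12 members of at least 10 RPKM and 3.40 over all 22 with a pseudocount of 0.1. CHS, chalcone synthase, rose from 11.1 to 326 RPKM, 29.5-fold (27.0 to 32.2). F3H, flavanone 3-hydroxylase, rose 48.2-fold to 93.6 RPKM, and CHIL, a chalcone isomerase-like protein, rose 42.9-fold to 119 RPKM. The span of another gene covered 100% of the F3H coding sequence. The summed reads of the list gave a ratio of 2.61. The abundant general phenylpropanoid genes PAL1, PAL2 and C4H, named after their values were seen, were not called. C4H was at 195 RPKM in darkness and 290.1 RPKM in red light, and PAL1 at 105 and 148 RPKM. Of 10 chloroplast transcription regulators, 6 rose, none fell and 4 were not called (median 1.49, percentile 100). CGA1, a GATA factor of chloroplast development, rose 49.7-fold (33.5 to 77.2) to 28.6 RPKM, and SIG5, a sigma factor of the plastid RNA polymerase, rose 24.3-fold to 73.5 RPKM.

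Photoreceptor and light-signalling genes moved in both directions. Of 33 members, 10 rose, 6 fell and 17 were not called. PHYA, the photoreceptor phytochrome A, fell from 601 to 159 RPKM, 3.77-fold (3.71 to 3.83), and FHY1, which carries phytochrome A into the nucleus, fell 7.24-fold from 161 to 22.2 RPKM. PIF3, a phytochrome-interacting transcription factor, fell 2.70-fold from 46.9 RPKM, while its relative PIF4 rose 4.49-fold from 13.6 to 61.1 RPKM. HYH, a homologue of the light-response regulator HY5, rose 10.9-fold to 107 RPKM. HY5 itself was below the threshold, at 79.6 RPKM in darkness and 139 RPKM in red light, a ratio of 1.75 (1.64 to 1.86). The list's median log2 change was 0.21 (percentile 99.6) and its mean 0.59, whereas the reads of all members together gave a red-to-dark ratio of 0.802. PHYA alone held 83266 of the list's 169895 reads in darkness.

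Many genes of shade and dark growth were lower in red light. Of 17 genes known to be induced by shade or by PIF proteins, none rose, 10 fell and 7 were not called (median log2 change -1.37, percentile 0). PIL1, a PIF-like transcription factor, fell from 36.2 to 1.96 RPKM, 18.5-fold (14.8 to 23.4). ATHB2, a homeodomain protein of shade avoidance, fell 9.04-fold from 82.6 to 9.14 RPKM. Of 20 auxin response genes, none rose, 8 fell and 12 were not called (median -0.72, percentile 0). IAA29 and IAA19, Aux/IAA repressor proteins that also stand in the shade list, fell 7.18-fold and 3.55-fold (3.35 to 3.77). GH3.3, an enzyme that conjugates auxin to amino acids, fell 5.14-fold from 11.5 to 2.24 RPKM.

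Cell wall loosening genes had equal numbers of rises and falls, with a median below the random lists. Of 22 expansins and xyloglucan endotransglucosylases, 6 rose, 6 fell and 10 were not called (median log2 change -0.56, percentile 0, mean -0.22). In the later family scan, over genes of at least 10 RPKM, 17 expansins had a median of 0.05 (percentile 87.1). There 18 xyloglucan endotransglucosylases had a median of -0.46 (percentile 0.49), so only the latter stood apart. The summed reads gave a red-to-dark ratio of 0.489, and XTH15 held 121796 of the list's 245026 reads in darkness. Beside XTH15, XTH5 fell 7.39-fold from 35.2 to 4.77 RPKM. EXPA1, an expansin, rose 7.89-fold from 50.7 to 399.9 RPKM, and EXPA10 rose 4.39-fold to 85.5 RPKM.

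Among the hormone lists other than auxin, that of ethylene had a median below the random lists. Differences between these lists were not tested. Of 8 ethylene and apical hook genes, none rose, 3 fell and 5 were not called (median log2 change -1.23, percentile 0, and -1.92 with a pseudocount of 0.1). HLS1, which maintains the apical hook, fell 8.70-fold from 23.6 to 2.71 RPKM, and ACS5, an enzyme of ethylene synthesis, fell 7.06-fold. The remaining called member, ACO1, an ethylene-forming oxidase outside the naming rule and chosen after its value was seen, fell 2.53-fold. Of 11 gibberellin genes, 2 rose, 2 fell and 7 were not called. GA2OX1, a gibberellin-inactivating oxidase, rose from 5 reads in darkness to 884 reads, or 26.6 RPKM, a ratio of 217 (92.5 to 669). GA2OX6, another enzyme of that class, fell 2.92-fold to 12.9 RPKM. GASA6, a gibberellin-regulated peptide, rose 2.82-fold to 1053 RPKM, and GASA4, a related peptide, fell 2.28-fold from 6182 to 2717 RPKM. The median of this list was 0.29 (percentile 97.8) and the ratio of its summed reads 0.609, so the direction depends on the summary. The list no longer stood apart with a pseudocount of 0.1 (percentile 95.5) or over its 8 members of at least 10 RPKM (percentile 91.2). Of 7 brassinosteroid genes, only CPD, a cytochrome P450 of hormone synthesis, was called, with a 3.06-fold fall to 87.2 RPKM (list median -0.10, percentile 51.6).

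Dark- and starvation-induced genes fell strongly. Of 9 such genes, 1 rose and 8 fell (median log2 change -2.24, percentile 0). DIN1, a senescence marker induced by darkness, fell from 1243 to 77.5 RPKM, with a counting interval of 15.2-fold to 16.9-fold. BCAT2, among the largest falls, is also a member. DIN9, a mannose-6-phosphate isomerase, rose 4.08-fold to 34.5 RPKM, against the rest of its list. Of 13 genes of fatty acid breakdown and the glyoxylate cycle, which turn seed oil into sugar, none rose, 2 fell and 11 were not called (median -0.33, percentile 7.88). The 2 were ICL, isocitrate lyase, which fell 4.82-fold from 515 to 107 RPKM, and PCK1, phosphoenolpyruvate carboxykinase, which fell 3.03-fold from 1079 to 357 RPKM. Only 1 of the 13 had a higher value in red light, and their summed reads gave a red-to-dark ratio of 0.461. PCK1 held 89382 of the list's 187253 reads in darkness.

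Clock genes showed few calls. Of 21, 3 rose, 1 fell and 17 were not called (median log2 change 0.33, percentile 99.8). ELF4, a component of the evening complex, rose 7.70-fold (6.31 to 9.48) to 63.0 RPKM. LNK1, a transcriptional co-activator of the clock, rose 6.61-fold to 58.2 RPKM, and COR27, a cold-regulated repressor in the clock, fell 5.62-fold from 36.0 RPKM. The remaining called member, GI (GIGANTEA), was outside the naming rule and chosen after its value was seen, and rose 2.49-fold. The clock was sampled at a single time in each condition.

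The medians of the cold and seed lists were also higher. Of 8 cold and abscisic acid response genes, 4 rose, none fell and 4 were not called (median log2 change 1.97, percentile 100). KIN2 and KIN1, small cold-induced proteins, rose 10.6-fold to 623 RPKM and 6.94-fold to 162 RPKM, and share over 25% of their coding 31-base words with another gene, so the split between them is uncertain. RD29A and RD29B, desiccation-responsive genes named after their values were seen, rose 5.95-fold and 2.94-fold. Of 8 heat shock genes, 2 rose and 6, all below 10 RPKM in both conditions, were not called (median 0.40, percentile 98.3). This list no longer stood apart with a pseudocount of 0.1 (percentile 96.7). The 2 that rose were the chaperones HSP70-4, at 3.75-fold, and HSP90.1, at 2.19-fold. The later family scan, made after the values were seen, held 10 heat shock genes of at least 10 RPKM. Of these, 5 rose and none fell (median 0.90, percentile 99.98). Related families of that scan did not stand apart. Of 15 DnaJ heat shock proteins, none rose and 2 fell (median -0.28, percentile 9.37). Of 13 HSP chaperones, 2 rose and none fell (median 0.10, percentile 88.8). Of 15 seed reserve and maturation genes, 1 rose, 1 fell and 13 were not called (median 1.37, percentile 100, and 2.17 with a pseudocount of 0.1), and those 13 were below 10 RPKM in both conditions. EM6, a late embryogenesis protein, rose 6.52-fold (3.97 to 11.3) to 10.8 RPKM, and ABI5, a transcription factor of abscisic acid signalling, fell 2.91-fold from 12.8 to 4.40 RPKM.

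Several marker lists had few members at 10 RPKM, the minimum for a call. Of 17 root markers 6 reached it, of 14 cell cycle genes 6 and of 8 stomatal lineage genes 2, and none of these was called, nor was the stomatal regulator SPCH, at 9.92 RPKM in red light, which was called higher under TMM and DESeq2 scaling. The list medians over all members were -0.10 (percentile 22.4), 0.19 (percentile 94.1) and 0.39 (percentile 98.2). None of the 4 pathogen defence genes reached the minimum, with 6 reads in darkness and 1 in red light over the list, so no call was possible (median -0.05, percentile 18.5). None of 13 reference genes was called (median -0.10, percentile 57.2). ACT2, an actin, was at 1696 RPKM in darkness and 1587 RPKM in red light. UBQ10, a polyubiquitin, was at 1737 and 2079 RPKM, a log2 change of 0.26 that became -0.02 under quantile normalization. Of 88 plastid-encoded genes, 86 reached 10 RPKM and none was called (median -0.27, percentile 0.7), and 17 of the 88 had a higher value in red light. Of 122 mitochondrion-encoded genes, only 14 reached 10 RPKM, and none of these was called. The median was -0.19 over all 122 (percentile 0) and also -0.19 over the 14, where its percentile was 29.0. Libraries were made from poly(A) RNA, which captures organelle transcripts poorly.

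**Figure D3:**
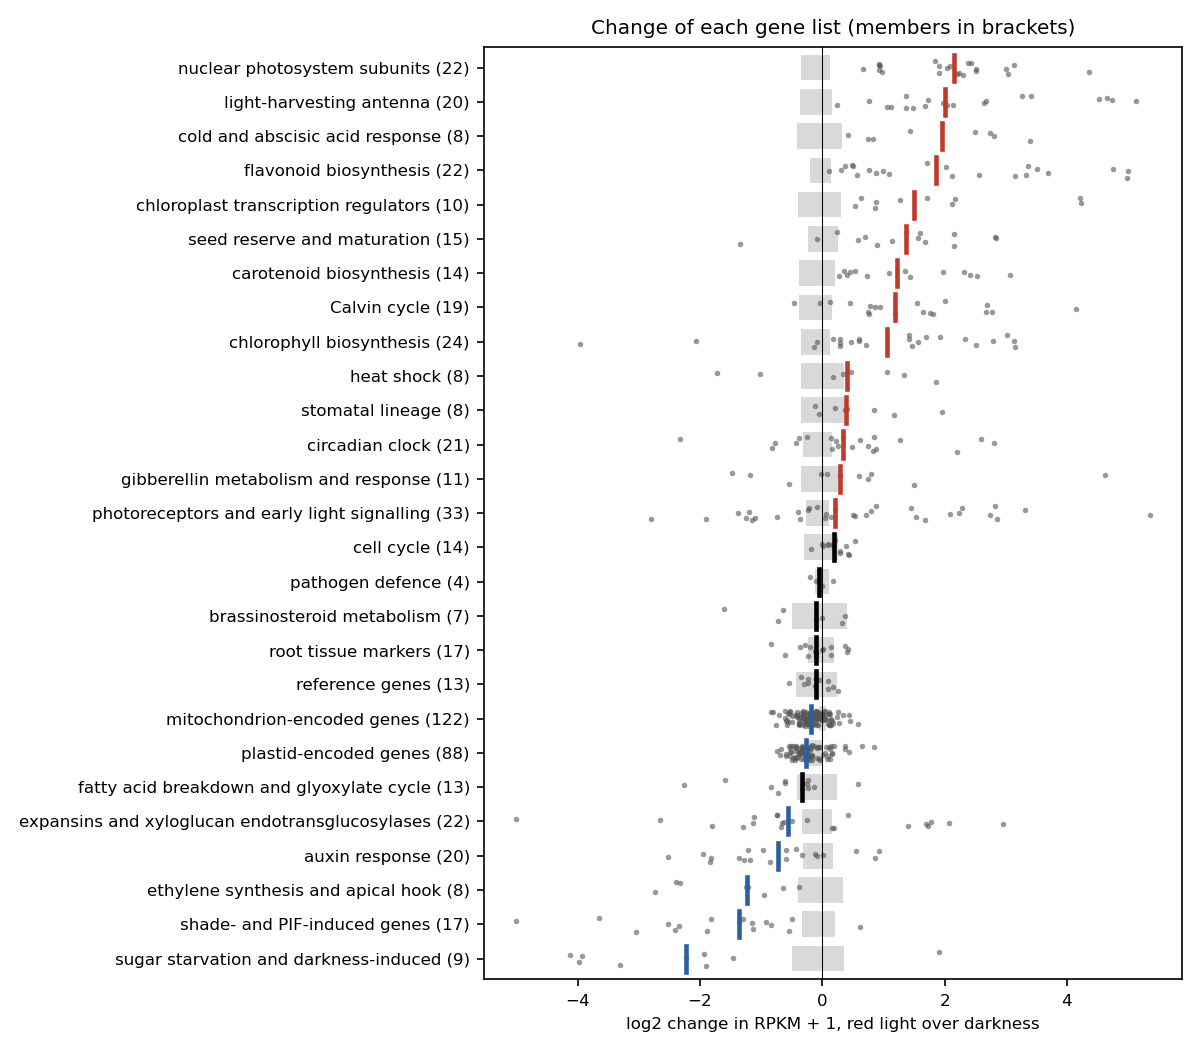
Log2 change in RPKM + 1 (red light over darkness) of each member of the 27 lists (grey points), with the list median as a bar, red above and blue below the central 95% of medians of 10000 random lists matched on expression (grey band) and black within it. Photosystem subunits (median 2.15) and antenna genes (2.01) lie at the top, and sugar starvation and darkness-induced genes (-2.24) at the bottom.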

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

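The alternatives with TMM scaling of calls, the 4-fold threshold, the whole interval, the shared-sequence genes, the photosynthesis genes, the scaling of list and B-box members and the list settings other than quantile normalization were chosen after seeing the data. Under 4-fold in place of 2-fold, 398 genes were higher and 124 lower, by construction fewer than the main 1097 and 676. The other 11 alternatives gave 996 to 1460 higher and 562 to 821 lower calls, all within 1.5 times the main counts. The extremes came from the interval rule (996 and 562) and from no minimum value (1460 and 821). TMM scaling gave 1209 and 574, DESeq2 size factors 1185 and 585, and the 574 and 585 were all among the main calls. The share of higher calls stayed between 60.8% and 68.0% in those 11. Of 474 recomputed changes of the 79 named genes, 393 moved by no more than the log2 half-width of the gene's counting interval, 81 moved by more and 0 of the called ones reversed. Of the 81, 23 came from TMM scaling, 18 from DESeq2 size factors, 16 from quantile normalization, 1 from upper-quartile scaling and 23 from a pseudocount of 0.1. Under that pseudocount the log2 change of AT1G26761 went from 5.22 to 7.82 and that of GA2OX1 from 4.62 to 6.91, by its construction for genes with few reads.

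List calls stayed at 14 higher and 7 lower under quantile normalization and TMM scaling. A pseudocount of 0.1 gave 12 and 7, losing gibberellin (percentile 95.5) and heat shock (96.7). With members of at least 10 RPKM alone, 10 and 6 stood apart. Gibberellin (91.2) and the mitochondrial genes (29.0) no longer did, and seed, stomatal, heat shock and defence lists had too few members to be ranked. The cause was not tested. No call of a named gene ended under TMM, DESeq2, upper-quartile or quantile scaling. Most named genes were chosen for large changes, and the median shifted by at most 0.07 on the log2 scale under these scalings. The kept calls and the absence of reversals under them therefore follow largely from the choice of genes and are no separate evidence. Among list members, RBCS2B, LHCB4.1 and LHCB4.2 lost their calls under quantile normalization. GH3.6 and SPCH gained a call under TMM, as did 4 photosystem subunits and CFBP1.

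No paired analysis was possible because each condition had 1 column of values. For that reason the DESeq2 and limma-voom tests, thresholds on adjusted p, camera with an estimated correlation, fry, the replicate block and leaving out each sample were not run. Depth limits statements on weak genes: a gene of median length without reads is bounded at 0.0697 RPKM in darkness and 0.0855 RPKM in red light by counting alone.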

Other observations

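The gene families described here, and the test of counting error, were chosen after the values were seen, while the other tests were written down before their results. Every family here, and in the scan below, was counted only over members with at least 10 RPKM in either condition. Weaker members are left out, so the counts are not shares of whole families. B-box zinc finger proteins, several of which act in light signalling, were among the most divided families. Of 26 with at least 10 RPKM in either condition, 10 rose, 6 fell and 10 were not called, with a median log2 change of 0.34 (percentile 99.8). BBX31 rose 95.3-fold to 25.3 RPKM (36.9 to 352, with 4 reads in darkness), BBX18 rose 12.4-fold to 39.9 RPKM and BBX24 rose 4.88-fold to 537 RPKM. BBX30 had 0 reads in darkness and 11.2 RPKM in red light. Beside BBX23 and BBX17, BBX28 fell 2.61-fold, BBX21 2.15-fold, COL9 2.11-fold and COL5 2.03-fold. The calls of COL9 and COL5 ended under TMM and DESeq2 scaling, which left 4 lower and 11 higher with COL1 added, and that of COL5 ended under quantile normalization. SAUR genes, small auxin-induced proteins linked to cell expansion, fell in 19 of 41 cases, rose in 3 and were not called in 19 (median -0.89, percentile 0). SAUR22 fell 5.57-fold from 58.5 to 10.5 RPKM, although AT4G38840 of the same family rose 9.85-fold to 178 RPKM. Several SAUR genes are near-identical neighbours, so their split of reads is uncertain.

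Some lipid-related families and the purple acid phosphatases had medians above the random range, although most members of each were not called. Of 29 GDSL lipases, 9 rose, none fell and 20 were not called (median log2 change 0.35), among them AT5G45950, which rose 9.43-fold to 221 RPKM. Of 14 ketoacyl-CoA synthases, which elongate fatty acids for waxes, 10 were not called, while KCS9, KCS16 and KCS2 rose 3.57-fold, 2.83-fold and 2.21-fold and KCS12 fell 3.75-fold, the KCS2 value being uncertain because another gene spans 76.6% of its coding sequence. Of 36 proteins annotated as lipid-transfer-like, 13 rose, 2 fell and 21 were not called. LTPG2 of this family, a membrane-anchored lipid-transfer protein, rose 3.03-fold from 109 to 331 RPKM. Of 10 fibrillins, proteins of plastoglobules, 4 rose, none fell and 6 were not called, with FIB4 going from 19.8 to 59.6 RPKM. Of 10 purple acid phosphatases, 4 rose and 6 were not called, with PAP8 at 5.27-fold and PAP10 at 4.16-fold. These came from a scan of 175 families, of which 24 lay above and 12 below the percentile limits. Families of genes drawn independently would place 4.38 on each side, and genes that vary together could exceed these limits more often.

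The most abundant transcript in darkness was AT3G52700, annotated as an uncharacterized protein, at 14576 RPKM in darkness and 10661 RPKM in red light. CA2, a carbonic anhydrase, was among the 8 most abundant in darkness and fell from 6643 to 2024 RPKM. LTP2, a lipid-transfer protein not counted in the lipid-transfer-like family above, fell from 5686 to 2344 RPKM.

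The rise of the 61 antenna, photosystem and Calvin cycle genes was set against a bias of GC content or coding length. All 61 had both values, and their median log2 change of 1.91 stood at percentile 100 among random lists matched on expression, GC content and coding length, which argues against that bias. An effect of red light may account for it as a hypothesis, but with 1 column per condition a difference between seedling batches or libraries was not tested and stays open.

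The 676 falls could in principle arise because photosynthesis genes took more of the reads in red light. Leaving these and the organelle genes out and rescaling both columns shifted the median of all genes by only 0.09 on the log2 scale, against a fall of at least 1 in each call, which argues against this as the main source. The number of calls kept, 563 of the 676 (83.3%), follows from that shift and is no separate evidence. The other 113 lay just beyond the threshold, and their median log2 change went from -1.04 to -0.96. An effect of the light condition on the rest was not tested apart from the libraries themselves.

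Seed reserve transcripts were few but mostly higher in red light, from 215 to 1445 reads over the 14 genes other than ABI5, which alone held 699 of the list's 914 reads in darkness and fell to 196, with CRA1 and CRC, seed storage globulins, at 24 and 7 reads in darkness and 433 and 362 in red light. The read numbers argue against counting error, since 86.7% of the 15 had an interval that excluded 1, 12 above it and 1 below. Seeds that had not germinated may have been more frequent in the red-light material: of a second list of dry-seed transcripts, 12 of the 14 with at least 10 reads (85.7%) were higher beyond counting error, LEA7 by 37.2-fold. BETA-TIP, which had the most reads of that list in darkness (1989, against 39 in red light), fell 41.6-fold. ABI5 of the first list fell 2.91-fold. More ungerminated seeds in the red-light material would not by themselves produce these 2 falls. However, the 1989 and 699 reads in darkness far exceeded the 215 of the other 14 genes of the first list together. If most of those reads came from outside seeds, the falls say nothing about seeds, so they cannot decide the question. Whether these 2 transcripts were made outside seeds was not tested, and the BETA-TIP value is uncertain because it overlaps another gene. A response of the seedlings to abscisic acid or to light itself stays open, since late embryogenesis genes are also induced by that hormone and 4 of 8 cold and abscisic acid genes rose.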
